A study of Gallus gallus with 4 samples.

How the data were processed

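Total RNA from 4 cultures of the chicken B cell line DT40 was labelled with Cy3 and hybridised to 4 one-colour Agilent arrays, 1 array per culture, per the labels. The cultures form 4 groups of 1 sample: parental DT40 without and with 500 µM indole-3-acetic acid (IAA), and DT40 stably expressing OsTIR1 without and with 500 µM IAA. Group membership was taken from the sample titles, which name the line and the IAA dose. What the untreated cultures received in place of IAA is not given in the sources used here.

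The deposited values are spot intensities on a linear scale, made with Agilent Feature Extraction 10.5.1.1, per the file headers. The software subtracted background, detrended each array over its surface and replaced signals too low to measure by a small positive value, so the processed intensity compares spots within an array and is not yet scaled between arrays, per the file headers. It also gives each spot an error estimate and a flag for being well above background. The headers name galGal2 as the genome build of the array grid. The series-level table of the deposit holds the same intensities multiplied by 1 constant per array, 4.40 and 4.63 for parental DT40 without and with IAA and 4.52 and 4.55 for the OsTIR1 line, which is a comparison of the files and not a stated step. Those columns had medians of 65.6, 58.8, 60.5 and 55.9. The direction and linear scale of that table follow from this match, and the reason for its constants stays unknown.

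Each array held 43451 spots, of which 1417 were control spots and 42034 carried 1 probe each. Control spots were left out of every count. No spot was saturated and none was flagged as an outlier. Signal was expressed as log2 of the processed intensity minus the array's own 75th percentile over the 42034 probes. That percentile lay at 177 and 168 intensity units for parental DT40 without and with IAA and at 171 and 168 for the OsTIR1 line.

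Probe names came from the array files and from a RefSeq name table of assembly GRCg7b, used for names alone. Of the 42034 probes, 66 carried a RefSeq accession, 51 of these matched the table, and they stand for 50 genes. Another 244 probes carried 118 chicken microRNA names. The other 41739 probes are unnamed here: 15 carry a RefSeq accession without a match in the table, and 41724 carry other sequence, cluster or design identifiers. Where a gene had several probes the one with the highest mean level was used, which concerned HSPA2 alone. Its probes had IAA differences of -0.04 and 0.00 in parental DT40 and 0.02 and -0.06 in the OsTIR1 line.

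The main choices, the gene lists and the rule for naming genes were written before the data were examined. The rule named, for IAA in each line, genes at least 2-fold different and well above background on both arrays, genes at least 1.5-fold different in both lines, genes past the threshold of the fit, the leading members of each list, genes at least 2-fold different between the lines both with and without IAA, and genes with a bound of at least 2-fold. It took TENM2, AVPR2, JUN and HSPA2. CYP1A4, CYP1A5, CYP1B1, AHRR, TIPARP, HMOX1, SKP1, CUL1, RBX1 and MYC were also to be named, and none has a named probe here. Other genes in the text were chosen after their values were seen.

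Counts of differences covered probes well above background on both arrays of a pair. A probe above background on 1 array of a pair has only a bound, the brighter level against the higher of the dim spot and the lowest level flagged well above background on the dim array. Differences of single genes carry a nominal 95% interval from the scanner software's error estimates of the 2 spots, which covers no variation between cultures. The interval rests on the error modelled by the software and not on a spread measured between replicate spots. Its half-width was 0.40 on the log2 scale for bright genes such as JUN, HSPA2 and CDK6 alike, and wider for dim ones. An interval that includes 0 therefore says little about a difference smaller than that. limma 3.58.1 in R 4.3.3 fitted a model with line and IAA terms to the 23100 probes well above background on at least 2 arrays. This fit has 1 residual degree of freedom and treats the lines as repeats of the treatment and the treatments as repeats of each line. Calls used a Benjamini-Hochberg adjusted p under 0.05. The crossed split, parental untreated with OsTIR1 treated against the other 2 arrays, is the interaction of line and IAA. It served as a reference for the size of differences, and a response to IAA in 1 line alone enters it as much as it enters the IAA split.

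The fit was tested on simulated data with 23100 probes and 200 changed ones. For IAA it called 0 of 50 probes changed by 1 on the log2 scale, 18 of 50 changed by 2 and 44 of 50 changed by 3, with 3 calls among unchanged probes. It called 0 of 50 probes changed by 0.58. Among the unchanged simulated probes, 78 were at least 2-fold different in both lines. Of the 19436 measured probes well above background on every array, 0 were so with IAA in the same direction. The simulated noise was therefore larger than that of these probes, and the counts of calls do not give the power of the fit for them. Probes of the fit that were measured on fewer arrays were not compared in this way.

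The 23 gene lists held 835 symbols, of which 4 have a named probe: JUN of the immediate early genes, HSPA2 of the chaperones, RAG1 of the B cell genes and TLR4 of the macrophage and granulocyte markers. The other 19 lists had 0 members measured: AhR and xenobiotic response, apoptosis, cell cycle, cholesterol and lipid synthesis, epithelial markers, endoplasmic reticulum stress and amino acid response, erythroid and thrombocyte markers, fibroblast and endothelial markers, glycolysis and hypoxia, growth arrest and DNA damage, interferon response, mitochondrial genome, oxidative stress, plasma cell markers, proteasome, ribosomal proteins, SCF ubiquitin ligase and cullin neddylation, T cell markers, and tryptophan and indole metabolism. No list was tested as a group for that reason.

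The alternatives were median scaling, quantile and cyclic loess normalization, normexp background correction with an offset of 50 followed by quantile normalization, 2 other filters on dim probes, the series-level table, averaging of probes per symbol, thresholds of 1.5-fold and 3-fold, an adjusted p under 0.1, and a limma prior with trend and robust estimation. Normexp ran on median spot intensities because the files used here carry no mean intensity column. With median scaling the median difference of the probes well above background on all arrays was 0.16 for IAA in parental DT40, 0.10 for IAA in the OsTIR1 line, 0.11 for the line without IAA and 0.06 for the line with IAA. The 4 arrays share 1 slide and 1 scan, and each group holds its own position on the slide, so position and group cannot be told apart.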

Results

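Gene expression was measured in DT40, a chicken bursal B lymphoma cell line, and in a stable DT40 line expressing OsTIR1, the rice F-box protein that binds auxin in plant cells. Cultures were grown at 38.5 °C in medium with 10% fetal calf serum and 1% chicken serum. Cells of each line were harvested 6 h after 500 µM IAA, the natural auxin, or as untreated controls. The question was whether auxin induces particular genes in animal cells as it does in plants. Each of the 4 groups is 1 array, so there are no replicates, and the number of arrays limits the precision of every value below.

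Of 42034 probes, 20086 (47.8%) were well above background in untreated parental DT40 and 20967 (49.9%) in IAA-treated parental DT40. In the OsTIR1 line these were 24359 (58.0%) without IAA and 23306 (55.4%) with it. Background was measured on the negative control spots before background subtraction. It was 34.9 and 26.0 intensity units in parental DT40 without and with IAA and 21.2 and 19.0 in the OsTIR1 line. The lowest intensity flagged well above background was 14.3 and 10.4 in parental DT40 and 5.71 and 6.12 in the OsTIR1 line. This intensity is background-subtracted, so it is not on the scale of the background values. All 4 arrays measured 19436 probes (46.2%) well above background. Spike-in transcripts added as controls gave 7 probes above background with 224 spots per array. Their mean levels differed by at most 0.07 on the log2 scale in the pairs of arrays compared for IAA or line. The dimmest of the 7 had a mean level of -2.20, so the spike-ins do not cover the dimmest probes. None of 896 pairs of spike-in spots was 1.5-fold apart.

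Among the 50 named genes, 22 were well above background on all 4 arrays, 4 on some arrays and 24 on none. EXOSC10, a subunit of the nuclear RNA exosome, stood 5.88 on the log2 scale above the array's 75th percentile in IAA-treated parental DT40. HSPA2, a chaperone of the HSP70 family, stood at 4.81 there, PDCD2 at 4.73, the cell cycle kinase gene CDK6 at 4.34 and JUN, the AP-1 transcription factor gene, at 4.12. RAG1, the recombinase gene of immature lymphocytes, TLR4, the lipopolysaccharide receptor gene of macrophages, and SOCS2, a feedback regulator of cytokine signalling, were not well above background on any array. VTG2, a yolk protein gene of the liver, and the hormone and neuropeptide receptor genes MC2R, MC4R, NPY1R and NPY2R were not either.

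IAA left the named genes of parental DT40 close to their untreated levels. JUN was 0.11 higher on the log2 scale with IAA (95% interval -0.29 to 0.51), HSPA2 0.04 lower (-0.44 to 0.36) and CDK6 0.01 higher (-0.39 to 0.41). Of the 22 genes above background on all arrays, 21 differed by less than 1.5-fold, from -0.23 for TGFB2 to 0.13 for PRLHR2. CHRM4, a muscarinic acetylcholine receptor gene, was the exception at -0.97 (-1.44 to -0.51). AVPR2, a vasopressin receptor gene, was above background in the untreated array alone, at least 1.94-fold above the treated one. CHRM4 and AVPR2 both lie in a part of the array surface where probes were unusually bright on the untreated parental array, and in untreated parental DT40 CHRM4 was also 0.95 above its highest level on the other arrays.

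Over all probes measured on both parental arrays, 98.1% differed by less than 1.5-fold with IAA. Of 19492 probes, 27 were at least 2-fold higher and 65 at least 2-fold lower (92 in all, 0.472%). Of the 92, 4 carry a microRNA name and none has a gene symbol here. Median scaling gave 38 higher and 39 lower. Leaving out the bright part of the surface and its neighbour, which is a choice made after the data were seen, gave 18 higher and 27 lower of 17098 probes. The 9718 brighter probes held 4 higher and 2 lower.

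IAA in the OsTIR1 line asked whether the plant receptor gives animal cells a response that parental cells lack. JUN was 0.12 higher with IAA (-0.28 to 0.52), HSPA2 0.02 higher (-0.38 to 0.42) and CDK6 0.02 lower (-0.42 to 0.38). TENM2 was 0.06 lower and TGFB2 0.22 lower (-0.62 to 0.18). All 22 named genes above background on every array differed by less than 1.5-fold, from -0.38 for CRHR1 to 0.23 for OLFR6. No interval excluded 0, but with half-widths from 0.40 upward none could do so for a smaller difference. Of 22873 probes, 32 were at least 2-fold higher and 45 at least 2-fold lower, none with a named gene, and 97.8% lay within 1.5-fold. Median scaling gave 46 higher and 36 lower, quantile normalization 44 and 36, and cyclic loess 43 and 38. Among the 19436 probes above background on all 4 arrays the counts were 7 higher and 17 lower, and the 9718 brighter of those probes held 0.

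**Figure D1:**
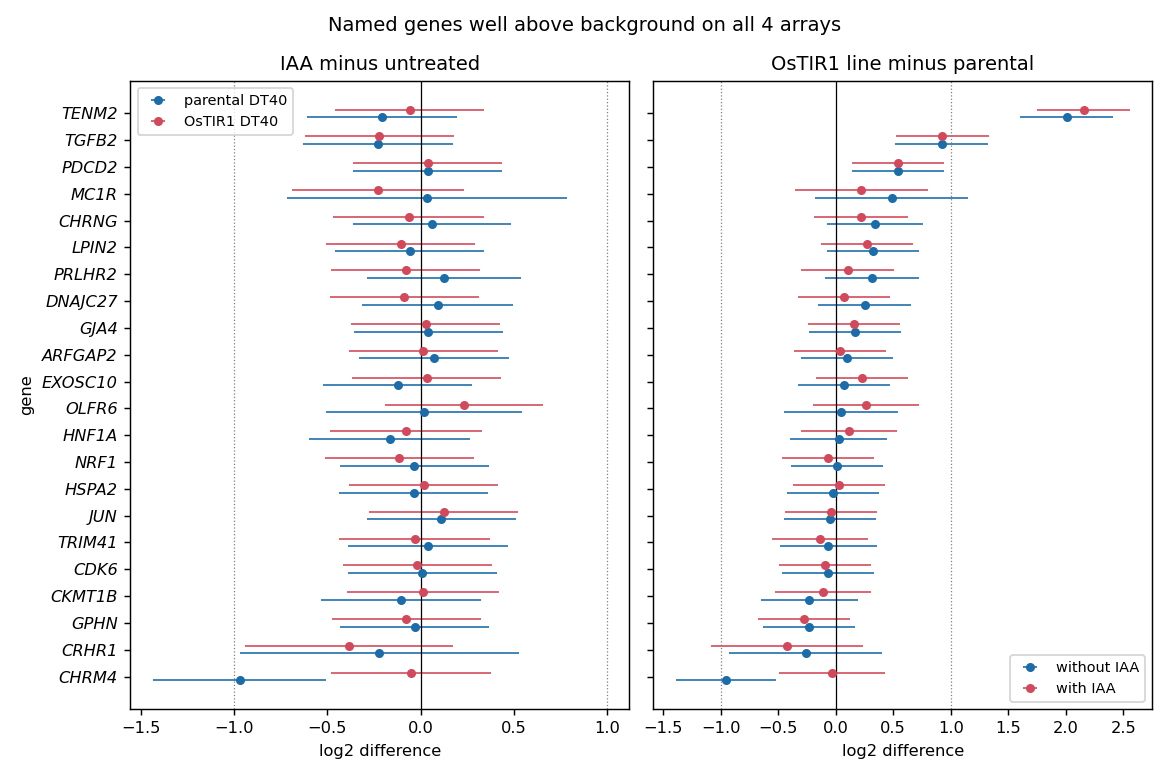
Differences of the 22 named genes well above background on all 4 arrays, with log2 difference on the x axis and genes on the y axis. The left panel shows IAA minus untreated in each line and the right panel the OsTIR1 line minus parental without and with IAA; bars are 95% intervals from the scanner software's spot errors and dotted lines mark 2-fold. TENM2 lies at 2.01 and 2.16 in the right panel, and CHRM4 at -0.97 in parental DT40 has no counterpart in the OsTIR1 line at -0.05. The CHRM4 probe lies in a part of the array surface where probes were unusually bright on the untreated parental array.

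No gene or unnamed probe above background on all 4 arrays met the 2-fold rule for IAA in both lines. At 1.5-fold, 0 probes were higher in both lines and 11 were lower in both, against 0.168 and 1.5 for independent lists of these sizes. In opposite directions in the lines, 5 probes passed 1.5-fold, against 1.01 for independent lists. These references take every probe as equally likely to pass. Differences sat mostly among dim probes, so the references are too low. Of the 11, 2 passed 1.5-fold in both lines with median scaling, 4 with quantile normalization, 6 with cyclic loess and 0 with normexp. The 11 carry no gene name, and all 11 lie below the median level of the 19436 probes. Of the 22 named genes, 13 had the same sign of IAA difference in both lines. Across the 19436 probes the IAA differences of the lines correlated with Pearson's r of 0.064 and Spearman's rho of 0.045, and r was 0.0039 over the brighter 9718; probes are not independent replicates.

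In the additive limma fit over both lines, JUN had an IAA effect of 0.12 and HSPA2 one of -0.01, neither past the threshold. The fit called 0 of 23100 probes for IAA, with 1125 at an unadjusted p under 0.05 where 1155 are expected by chance. The smallest adjusted p was 0.955. A limma prior with trend and robust estimation called 2 probes higher and 6 lower with IAA, and normexp correction with quantile normalization called 51 higher and 58 lower, none with a named gene. Of the 109 normexp calls, 4 reached 1.5-fold. The 8 trend and robust calls had a median size of 3.28 on the log2 scale, fitted against arrays where the probes were not well above background. Of these, 6 were lit in both untreated cultures alone and 2 in both treated cultures alone, with bounds from at least 1.59-fold to at least 6.24-fold in a line. They were dim where lit, at 13.1 to 40.0 intensity units, and 5 of the 8 lie in the bright part of the parental array surface or its neighbour. The crossed term, fitted in the same way, gave 0 calls in each of these 3 settings.

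Detection on its own was also compared. In untreated cultures of both lines but in neither treated one, 53 probes were well above background, and 22 showed the opposite. The crossed pairs of arrays gave 13 and 83 such probes, 96 in all against 75 for IAA. With a bound of at least 2-fold in both lines, 8 probes were brighter in the untreated cultures and 0 in the treated ones, and the crossed pairs gave 1 and 0. None of these counts includes a gene named here. Probes dark on the other arrays were lit more often in the bright part of the untreated parental array. The lowest intensity flagged well above background also differed between arrays. These counts can therefore not be set down to IAA alone.

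Among probes measured on both arrays of a pair, more differed by at least 2-fold between the OsTIR1 line and parental DT40 than with IAA in either line. TENM2, a transmembrane cell adhesion protein gene, was 2.01 higher on the log2 scale in the OsTIR1 line without IAA (1.61 to 2.41) and 2.16 higher with IAA (1.75 to 2.56), a 4.23-fold fitted difference. It was the one named gene at least 2-fold apart in both comparisons. TGFB2, a growth factor gene, was 0.92 higher without IAA (0.52 to 1.32) and 0.93 higher with it (0.53 to 1.33). PDCD2 was 0.54 higher in both comparisons. TGFB2 and PDCD2 were picked after their values were seen. JUN was 0.05 and 0.04 lower in the OsTIR1 line, and HSPA2 was 0.02 lower and 0.03 higher, without and with IAA.

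CHRM4 was 0.95 lower in the OsTIR1 line without IAA and 0.04 lower with it, and AVPR2 was at least 3.60-fold lower without IAA, both set by the untreated parental array. The largest difference was at the unnamed probe BU322203, with 805 and 850 intensity units in parental DT40 and 11.5 and 11.4 in the OsTIR1 line without and with IAA, 67.8-fold and 74.3-fold lower. Probe CR352358 was 14.7-fold and 14.5-fold lower. On the other side, probe AJ719272 was 5.42-fold and 5.71-fold higher and probe CR389789 5.93-fold and 5.35-fold higher.

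Without IAA, 429 of 19709 probes were at least 2-fold different between the OsTIR1 line and parental DT40, 324 of them lower in the OsTIR1 line. Of the 324, 111 lie in the bright part of the untreated parental array and its neighbour, which hold 12.2% of all probes, and leaving both out gave 90 higher and 213 lower of 17226. With IAA, 106 of 20604 were higher and 216 lower, 26 of the 216 in these parts. TENM2 was among 55 probes at least 2-fold higher in both comparisons, and 92 probes were lower in both. The references for independent lists, again too low where differences are mostly dim, were 0.472 and 1.43. Median scaling gave 70 higher and 79 lower, and normexp correction 27 and 27. Line differences with and without IAA, which share no array, correlated with Pearson's r of 0.682 and Spearman's rho of 0.539 across 19436 probes, and of the 22 named genes 20 kept their sign. Of probes lit on 1 array of a pair, 465 and 386 had a bound of at least 2-fold for the line without and with IAA. For IAA in parental DT40 and the OsTIR1 line these were 451 and 291, so these counts lay closer together. The untreated parental array was the lit one in 377 of the 465 and 367 of the 451. Its bright part alone held 124 of the 322 probes lit on that array only, so the patch enters both counts. The line split gave 210 probes at least 2-fold apart (79 higher, 131 lower), the IAA split 10 (2 higher, 8 lower) and the crossed split 4 (2 and 2).

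In the limma fit TENM2 had an adjusted p of 0.0906 for the line, TGFB2 0.111, PDCD2 0.146 and CHRM4 0.442. No probe reached an adjusted p under 0.05, the smallest being 0.0855, shared by BU322203, CR352358 and other probes. An unadjusted p under 0.05 was found for 4333 of 23100, where 1155 are expected. The call count depended on the setting, with 910 when the fit was limited to probes above background on all 4 arrays, 2970 with trend and robust estimation, and 2795 with normexp correction. Each line is 1 culture per treatment, so these counts compare these cultures. Probes above background in the OsTIR1 line alone numbered 2090 and in parental DT40 alone 37, beside the lower background of the OsTIR1 arrays.

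**Figure D2:**
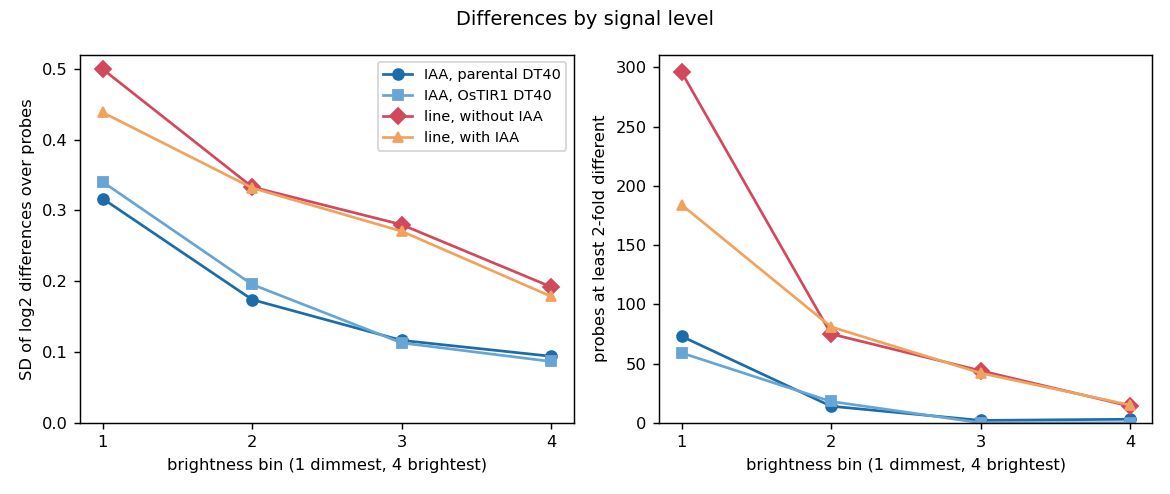
Spread and size of differences by signal level, with 4 bins of equal size, from dim to bright, of the probes of each comparison on the x axis. The left panel plots the SD of log2 differences over probes and the right panel the number of probes at least 2-fold different; each line is 1 comparison of 2 arrays. For IAA the SD goes from 0.317 and 0.340 in the dimmest bin to 0.094 and 0.087 in the brightest.

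Differences of 2-fold with IAA sat among dim probes. With the probes in 4 bins of brightness, the dimmest bin of parental DT40 held 17 of the 27 higher and 56 of the 65 lower ones, and the brightest bin 3 and 0. In the OsTIR1 line the dimmest bin held 27 of the 32 higher and 32 of the 45 lower ones, and the brightest bin 0. Line differences were also mostly dim, with 296 of 429 without IAA (69.0%) and 184 of 322 with IAA (57.1%) in the dimmest bin, against 79.3% and 76.6% for IAA in parental DT40 and the OsTIR1 line. Bright probes differed too between the lines, with 12 higher and 2 lower in the brightest bin without IAA and 15 higher and 0 lower with IAA.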

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

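The tests of this part were chosen after the results were seen, except the test of the bright patch, whose measure was predicted before it was computed but after the crowding had been seen. The control probe ETG05_66023, one of the built-in control sequences of the array that no comparison uses, was well above background on 39 of its 40 spots over the 4 arrays. Its median level was -2.97 and -2.95 in parental DT40 and -2.89 and -2.87 in the OsTIR1 line, without and with IAA. The other 28 control sequences of these kinds were above background on at most 3 of 40 spots, at levels near those of the negative controls, -5.61 in untreated parental DT40. No explanation was tested for this signal, and it did not separate the groups.

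Probes at least 2-fold different with IAA in 1 line are the first pattern weighed, and a local defect on the untreated parental array is a candidate explanation for many of the parental ones: 2 adjacent parts of the surface, of 16, held 47 of the 92 probes and 12.2% of all probes. Of the probes dark on the other 3 arrays, 11.8% were lit on that array in the more crowded part and 11.2% in its neighbour, against at most 1.89% in the other 14. In 41 of the 45 differences there that all arrays measured, the untreated array stood apart from the OsTIR1 arrays. A response of parental DT40 to IAA would set the treated array apart in most of them. These are neighbouring spots in parts chosen for their calls, so the count is what a bright patch gives. It does not exclude a response at single probes. On the rest of the surface the untreated array stood apart in 24 of 40 (95% interval 43.3% to 75.1%), which leaves a response open. Low signal may account for much of the remainder, since 95.3% of it, 37 of these 40 parental differences and 24 of 24 in the OsTIR1 line, lay below the median level of the probes. That share alone does not mark noise. Of the 147 line differences of at least 2-fold that recurred with and without IAA, only 42 lay among the 9718 brighter probes. In the OsTIR1 line the untreated array stood apart in 14 of 24 differences, so a response there and noise cannot be told apart on 24 probes.

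The 11 probes at least 1.5-fold lower with IAA in both lines are the second pattern. A lower background on the IAA arrays stays open: the median drop of the 11 in the OsTIR1 line was 15.5 units of signal (95% interval 8.24 to 23.2) against a fall of 2.27 in the negative controls, but 1.5-fold above the lowest signal counted already requires a drop of 3.12, so the comparison decides nothing. In parental DT40 the median drop was 14.01 (10.2 to 28.0) against a fall of 8.87. The same rule requires a drop of at least 5.47 there, and a larger one for brighter probes, so this comparison decides nothing either. In both lines the scales also differ: the drop is in background-subtracted signal, the fall in negative control signal before subtraction. On the log2 scale of processed signal, negative controls had medians of -7.00 and -6.84 in the OsTIR1 line without and with IAA. In parental DT40 these were -5.61 and -6.04. Processed signals too low to measure are replaced values, so these medians do not decide it. Besides, 5 of the 11 dim probes lay in the crowded parts of the surface, which were bright on the untreated array. The 11 stayed lower in both lines under median scaling, with median differences of -0.53 in parental DT40 and -0.66 in the OsTIR1 line against -0.70 and -0.76. Normexp correction, whose offset shrinks dim differences by construction, gave -0.15 and -0.22 with 10 of the 11 lower in both lines. Fewer still passed 1.5-fold in both lines: 2 with median scaling, 4 with quantile normalization, 6 with cyclic loess and 0 with normexp. A response to IAA in both lines stays open, because the smallest adjusted p of the 11 was 0.955 and a p of that size excludes nothing.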

How the results depend on the processing

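The restriction to the 9718 brighter probes, the percentile over probes detected on all arrays, averaging per identifier and leaving out 2 parts of the surface were chosen after the data were seen. The line split outnumbered the IAA split in every setting run, and IAA in both lines gave 0 probes at 2-fold except without a background filter; the cause was not tested for any change below unless named. With normexp correction IAA gave 7 probes in parental DT40, 0 in the OsTIR1 line and 109 in the fit, the line 54 in both comparisons and 2795 in the fit, the splits by IAA, line and crossing 0, 61 and 1, and the correlations -0.055 for IAA and 0.722 for the line. Its offset shrinks differences of dim probes by construction. Without a background filter these were 3091, 2921 and, in both lines, 318 for IAA, 1308 for the line, 1827, 10576 and 1496 for the splits, and 0.021 and 0.489 for the correlations, with probes at background entering. At 1.5-fold IAA gave 372, 500 and, in both lines, 11, the line 531 and the splits 95, 824 and 71; at 3-fold 14, 21, 45 and 0, 55 and 0. Among the brighter probes IAA gave 6 and 0, the line 42 and in the fit 2136, the splits 0, 49 and 1, and the correlations 0.0039 and 0.810. Probes above background on all arrays gave 24 for IAA in the OsTIR1 line and 910 in the line fit, trend and robust estimation 8 for IAA and 2970 for the line, and an adjusted p under 0.1 gave 72 for the line. Median scaling gave 7 for the crossed split, and the IAA correlation was 0.028 with quantile and 0.026 with cyclic loess normalization. Without the 2 parts of the surface IAA gave 45 in parental DT40, the crossed split 1 and the line correlation 0.701. Of 192 values of 8 named genes, 190 stayed within the interval of the gene's own value, which has a half-width from 0.40 upward and so holds any small shift. The values of CHRM4 with normexp were -0.40 for IAA in parental DT40 and -0.42 for the line without IAA. Leaving out 1 array was not run, since the fit then has no residual degrees of freedom, nor was a slide block, as there is 1 slide. The gene list alternatives were not run, since no list had over 1 member measured. No paired analysis was possible because each group has 1 replicate number, other than through the line term of the fit, which sets IAA against untreated within each line. Signal over background limits the dim probes: IAA differences had an SD of 0.317 in the dimmest of 4 bins in parental DT40 and 0.094 in the brightest.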

Other observations

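The tests of this part were all chosen after the results were seen. The 244 probes with chicken microRNA names are probes on a total RNA array and were left out of the gene accounts above. Between untreated and IAA-treated parental DT40, 218 of the 244 were higher with IAA, with a median difference of 0.11, while 10000 random lists matched on level had medians from -0.01 to 0.02 for the middle 95%. In the OsTIR1 line 137 of 244 were higher with IAA, with a median of 0.01, and in the line comparison 219 were higher without IAA (median 0.11) and 140 with it (median 0.01). The array of untreated parental DT40 is the one that sets both shifts. Of the 4 microRNA-named probes at least 2-fold different with IAA, all in parental DT40, mir-183 and mir-148a were higher by 1.80 and 1.75 and mir-125b and mir-206 lower, at -1.42 and -1.06. The second probe of each name differed by 0.16, 0.21, 0.08 and 0.21, so the differences were not shared by both probes of a name. The cause was not tested.

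All 244 microRNA-named probes were well above background on every array, against 46.2% of all probes, which is the third pattern weighed. They include 42 of 42 probes for microRNAs known from liver, muscle, brain, embryo or pancreas, such as mir-122a, mir-206 and mir-9, a count that is fixed once every such probe is lit and so decides nothing. Their levels were also close together, with an SD of 0.65 against 2.94 for the other probes lit on all arrays and 91.0% against 22.2% within 1 log2 unit of the median, but levels of different probes are not on a common scale and decide nothing here. A share of 100% lit leaves no room for the tissue-restricted names to differ, so signal that does not come from the named microRNA and expression of the named loci in DT40 cannot be told apart.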
